A study of Solanum lycopersicum with 9 samples.

How the data were processed

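RNA was sequenced from the locular tissue of tomato fruit, the gel-like tissue that surrounds the seeds, in the dwarf cultivar Micro-Tom. Fruits were harvested 6 days after anthesis from the wild type (WT) and from 2 CRISPR-edited lines of SlZFP2, named c2.5 and c2.11. Each genotype had 3 libraries, and each library pooled tissue of 6 fruits with the developing seeds removed, per the labels' protocols. The series' design text calls the libraries biological replicates, and neither it nor the labels say whether the pools came from separate plants, growing positions or days. If they did not, the p-values measure only the spread between these pools. Libraries were stranded mRNA libraries read as pairs of 150 bases on a DNBseq instrument, per the labels' protocols.

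The deposited file is a table of raw whole-number counts per gene, one column per library, for 34075 genes. FastQC and featureCounts are named in the submitters' processing notes, without versions or settings. The aligner, genome build, annotation and strand setting are not given in the sources used here, so no coordinates are given. Without the strand setting and the treatment of multiply mapped reads, counts of overlapping, antisense and near-identical genes cannot be separated from one another. All 34075 rows carry a gene identifier, and 8494 had no count in any library.

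The count table gives Solyc identifiers alone, and 0 of them were matched by the reference table used here (RefSeq assembly SLM_r2.1, 41476 genes), which holds neither these identifiers nor gene descriptions. The 28 lists of pathway, cell type and stress genes fixed before the data were examined search gene descriptions, so 0 of them could be applied, markers of seed, epidermis and vascular tissue included. A list of 18 known regulators with their identifiers, also fixed in advance, needs no descriptions, but only SlZFP2 was taken from it. SlZFP2 is reported as Solyc07g053570, a pairing that comes from general knowledge of the gene, was written down before the data were examined and is stated by neither table. The reference table places ZFP2 on chromosome 7, and the identifier carries the same chromosome number. Otherwise at most 2 identifiers per direction are named. The chromosome and the order of genes were taken from the digits of the identifiers.

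Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 3 genotypes, which left 19358 genes. Library sizes were scaled by TMM, and the quasi-likelihood test (robust glmQLFit, glmQLFTest) was fitted over all 9 libraries, so that the genotypes shared one estimate of the spread. The contrasts were the mean of both lines against WT, each line against WT, and c2.11 against c2.5. The threshold was an adjusted p (Benjamini-Hochberg over all genes tested) of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Normalized CPM are counts relative to the TMM-scaled library size. Named genes other than SlZFP2 were the 2 highest and the 2 lowest of those past the threshold and at least 2-fold changed the same way in both lines, with a mean of at least 1 CPM in some genotype, ranked by the smaller of their log2 fold changes in the 2 lines. The rule asked for a gene description, a part that could not be applied.

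Shares of counts were compared between libraries with two-sided exact permutation tests (scipy 1.17.1), where 3 libraries against 3 cannot reach a p below 0.1. Overlaps between the lines were set beside 20 simulations in which 2 unchanged lines were tested against the same simulated WT libraries. All counts were drawn gene by gene from a negative binomial model, so deviations that many genes share within a real library were not simulated. The 3 WT libraries could not be split into parts of 2. On simulated counts of the same 19358 genes with 200 genes changed, the test of both lines against WT recovered 62.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 11 false calls among 175. The test of c2.11 against c2.5 recovered 59.7%, 79.1% and 93.9% of the same classes. The changed genes were drawn only from genes above a minimum expected WT count. Far fewer genes were changed than were called in the data, so these rates do not hold for all tested genes. Alternatives fixed in advance were DESeq2 1.42.0, median-of-ratios size factors, other low-count filters, fits on the compared genotypes only, the replicate number as a block, a 2-fold minimum and the removal of each library in turn. Total count scaling and removal of the 100 most abundant genes were chosen after seeing the data. So were the descriptions by abundance quartile, chromosome, neighbouring genes and share of the most abundant genes, and the search for genes at least 4-fold higher in 1 library than in both others of its genotype (at least 1 CPM, with 0.1 CPM added to each value).

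No library duplicated another of its genotype, since the chi-square per degree of freedom between libraries of a genotype was 4.43 or more.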

Results

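The study compared gene expression in the young locular tissue of WT tomato fruit with that of 2 lines edited in SlZFP2, a zinc finger transcription factor, to describe early changes in the program that shapes this tissue. The 9 libraries held between 19963325 and 20727310 counts. Between 22331 and 22960 genes had at least 1 count in a library, and 19358 genes entered the tests. Total counts did not separate the genotypes (exact two-sided permutation test of 6 line libraries against 3 WT libraries, p = 0.833, adjusted p = 0.833 over 6 library measures).

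The WT libraries and the libraries of the edited lines formed separate clusters. The first principal component of the log2 CPM held 71.5% of the variance and ran from -43.2 to -29.7 in the 6 line libraries and from 74.0 to 81.7 in the 3 WT libraries. The second component held 7.75%, and c2.5 replicate 2 lay farthest from the other libraries on it, at -36.5. Spearman correlations of counts over tested genes were 0.993 to 0.995 between libraries of c2.5 and 0.943 to 0.956 between line and WT libraries. The WT libraries differed more among themselves than the line libraries, with a chi-square per degree of freedom of 10.9 or more between WT libraries and of 4.43 to 9.13 between libraries of a line.

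**Figure D1:**
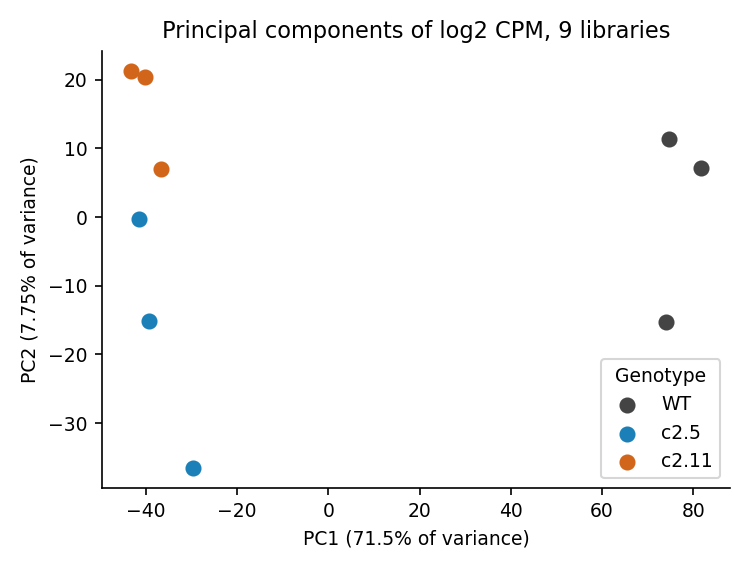
Scores of the 9 libraries on the first and second principal components of log2 CPM, 1 point per library, coloured by genotype. The 3 WT libraries lie between 74.0 and 81.7 on the first component and the 6 line libraries between -43.2 and -29.7.

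SlZFP2 transcripts were not lower in the edited lines. The gene (Solyc07g053570.4, chromosome 7) was counted at low depth, with 11 to 21 counts per WT library, 15 to 31 per c2.5 library and 30 to 49 per c2.11 library. Its level was 0.839 ± 0.267 normalized CPM in WT, 1.18 ± 0.406 in c2.5 and 1.74 ± 0.446 in c2.11 (SD, n = 3 libraries each). In c2.11 it was higher than in WT by 1.04 ± 0.34 on the log2 scale (SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0190), a call that ended without c2.11 replicate 2 (0.0887), WT replicate 2 (0.0571) or WT replicate 3 (0.0722). The difference in c2.5 was 0.48 ± 0.35 (edgeR adjusted p = 0.276) and did not pass the threshold, and the difference between the lines was 0.56 ± 0.32 (edgeR adjusted p = 0.442). For both lines together the log2 difference was 0.76 ± 0.31 (edgeR adjusted p = 0.0487). Over the alternatives this adjusted p ranged from 0.00992 to 0.173, and the call ended with DESeq2 (0.0808), median-of-ratios factors (0.0504) or the replicate block (0.0602), and without c2.11 replicate 1 (0.0608) or 2 (0.1004), c2.5 replicate 1 (0.0978) or 3 (0.0938), or WT replicate 2 (0.135) or 3 (0.173). A small edit need not change the amount of transcript, and the edited bases cannot be seen in counts, so these values do not check the genotype labels.

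**Figure D2:**
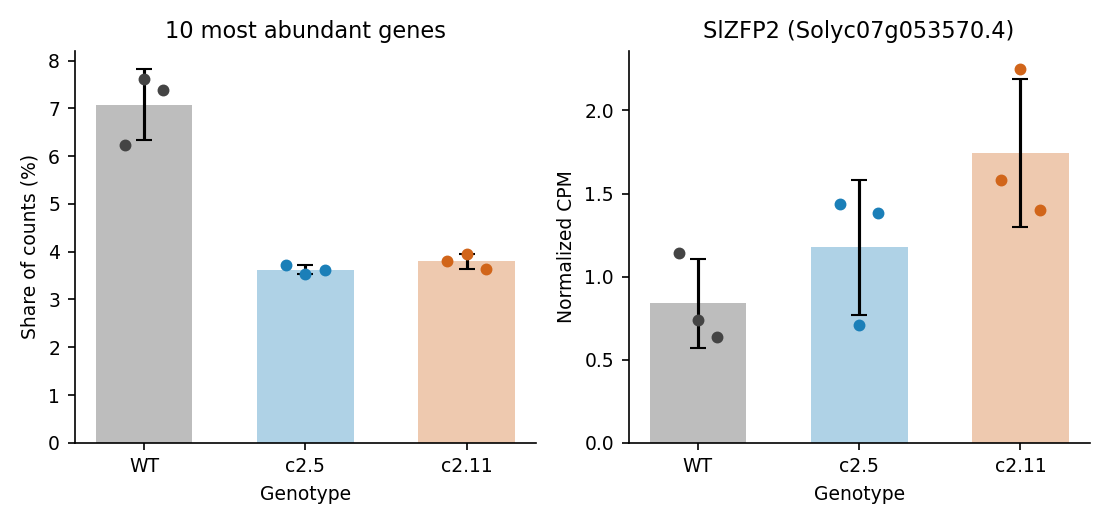
Left, the share of counts in the 10 most abundant genes of each library (percent), and right, the normalized CPM of SlZFP2, by genotype. Bars are means, error bars are SD and points are single libraries (n = 3). The share is 6.24% to 7.61% in the WT libraries and 3.53% to 3.95% in the line libraries, and SlZFP2 lies at 0.839, 1.18 and 1.74 normalized CPM.

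Against WT, both edited lines together showed 11052 changed genes, 57.1% of those tested. Of these, 5523 were higher and 5529 lower (edgeR quasi-likelihood test, adjusted p under the threshold of 0.05). At least 2-fold changes were seen in 1438 higher and 1352 lower genes, and at least 4-fold changes in 275 higher and 457 lower genes. The median size of a called change was 0.53 on the log2 scale. These directions are relative to the median gene, since TMM centres the median log2 change (0.01). With total count scaling the median of all tested genes moved to 0.29, and 10754 genes were called higher and 2940 lower, so that 78.5% of the calls were higher. The directions below are relative to the median gene except where total count scaling is named.

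The most abundant transcripts took a smaller share of the counts in the edited lines than in WT. The single most abundant gene took 2.12% ± 0.338 of the counts in WT (SD, n = 3 libraries) and 0.759% ± 0.0479 in the lines (n = 6). The 10 most abundant genes of each library took 7.08% ± 0.734 in WT and 3.71% ± 0.148 in the lines, and the 100 most abundant took 21.1% ± 1.22 and 14.4% ± 0.206. All 3 shares were higher in each WT library than in any line library (exact two-sided permutation test, p = 0.0238, the smallest this design allows, adjusted p = 0.0357). Of the 10 genes with the highest mean count, 7 were lower in the lines, 2 higher and 1 not called, and with total count scaling 7 were lower and 3 higher. Among the 100 with the highest mean count, 66 were lower and 18 higher, and with total count scaling 52 were lower and 30 higher.

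Across all tested genes the balance of directions moved with abundance. In the lowest quartile by mean CPM (0.234 to 5.03), 24.6% of genes were higher and 19.4% lower. In the highest quartile (45.7 CPM and more), 27.6% were higher and 40.2% lower. With total count scaling the balance of the highest quartile flipped, and higher genes outnumbered lower genes in each quartile, with 38.6% against 13.5% in the lowest and 59.8% against 21.7% in the highest.

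**Figure D3:**
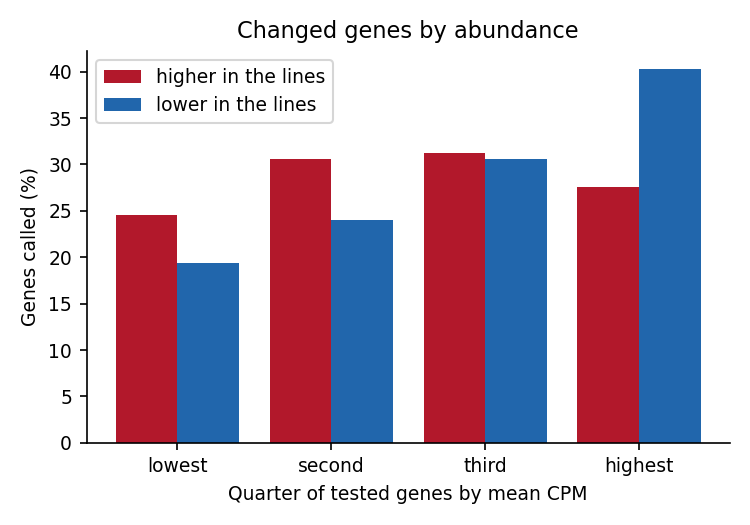
Share of tested genes called higher or lower in both edited lines against WT (percent), by quartile of mean CPM over the 9 libraries. Lower genes make up 19.4% of the lowest quartile and 40.2% of the highest, while higher genes make up 24.6% and 27.6%, a balance that flips in the highest quartile with total count scaling (59.8% higher).

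The largest changes went both ways: some genes scarce in WT were abundant in both lines, and 2 genes with at least 1 CPM in each WT library had no count in any line library. Solyc08g074630.2 on chromosome 8 was 200.3-fold higher in the lines, at 3.30 ± 0.198 normalized CPM in WT, 612 ± 36.2 in c2.5 and 711 ± 171 in c2.11 (SD, n = 3 libraries each), a log2 change of 7.64 ± 0.22 in both lines together (SE, edgeR adjusted p = 1.56e-08). Solyc09g065620.3 on chromosome 9 rose from 0.876 ± 0.362 in WT to 98.2 ± 3.09 in c2.5 and 94.4 ± 17.1 in c2.11, a log2 change of 6.76 ± 0.22 (edgeR adjusted p = 1.69e-08). In the other direction, Solyc01g090300.2 on chromosome 1 had 75 to 101 counts in each WT library and 0 in all 6 line libraries. Its WT level of 4.88 ± 0.745 normalized CPM (n = 3) makes it at least 210-fold lower in the lines, against a floor of 3 counts over the 6 line libraries (edgeR adjusted p = 1.37e-07). Solyc09g015070.3 on chromosome 9 was also at 0 in all 6 line libraries, but its WT counts of 74, 359 and 224 varied, and it was at least 537-fold lower by the same floor (edgeR adjusted p = 0.0243). That call was lost without WT replicate 3 (edgeR adjusted p = 0.138, with 1.79e-05 to 0.138 over the removals of single libraries). These genes were the top 2 of 1076 higher and of 1080 lower genes that met the naming rule, and what they encode is not stated in the sources used here. The floors cover counting error only.

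The change was spread over the chromosomes. The share of tested genes called in both lines together ran from 54.2% on chromosome 11 to 58.9% on chromosome 5, and the numbers of higher, lower and uncalled genes did not differ detectably between the 12 numbered chromosomes (chi-square statistic with calls shuffled over genes, 2000 permutations, p = 0.400). The lowest and highest shares of lower genes were 25.5% on chromosome 11 and 30.7% on chromosome 12.

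Each line showed the change on its own. In c2.5, 9667 genes differed from WT, 4812 higher and 4855 lower. In c2.11, 10569 genes differed, 5284 higher and 5285 lower (edgeR, adjusted p under the threshold of 0.05). At least 2-fold changes numbered 1365 higher and 1273 lower in c2.5, and 1528 higher and 1357 lower in c2.11. With total count scaling 10270 genes were higher and 2579 lower in c2.5, and 9952 higher and 2850 lower in c2.11. Whether the numbers of c2.5 and c2.11 differ was not tested.

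The lines shared most of their changed genes. Both lines changed 8544 genes in the same direction, 4172 higher and 4372 lower, and 2286 of all tested genes changed at least 2-fold the same way in both. With total count scaling 9084 were higher and 2300 lower in both. Independent lists of these lengths would share 1313 higher and 1325 lower genes. Unchanged lines simulated with a common simulated WT shared at most 1 gene. That number is no measure for the 8544, since unchanged genes are rarely called at all. Over all tested genes the fold changes of the lines correlated at r = 0.905, beside 0.512 on average for simulated unchanged lines, since both use the same WT libraries. Genes are not independent replicates. The covariance was 0.789 beside a simulated 0.0340, a difference of 0.755. The lines had the same sign in 88.0% of genes, beside 67.1% in the simulations. Part of the overlap may come from the shared WT libraries, which are too few to split.

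**Figure D4:**
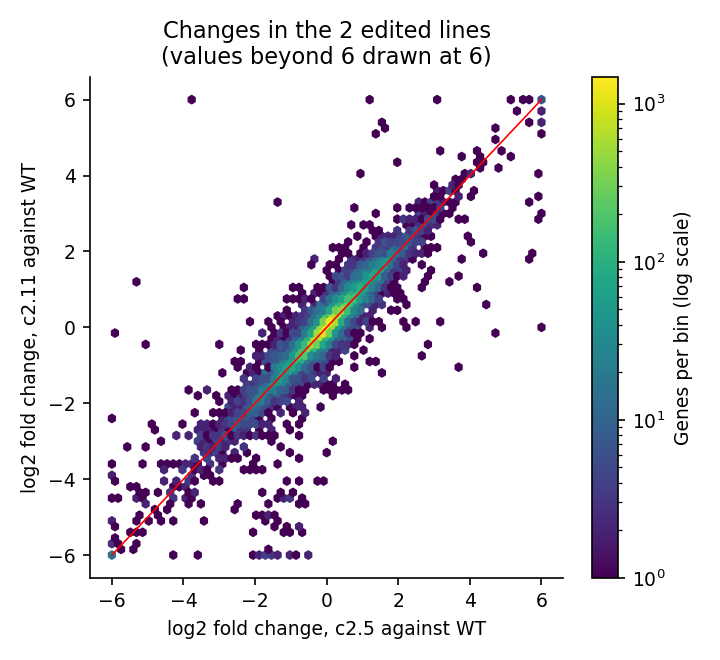
Log2 fold change against WT of each tested gene in c2.5 (horizontal) and c2.11 (vertical), as gene counts per hexagon on a log colour scale, with values beyond 6 drawn at 6 and the line of equal change in red. Most of the 19358 genes lie along the line of equal change (r = 0.905 across genes).

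A direct comparison called few genes different between the edited lines. Between c2.11 and c2.5, 249 genes differed, 137 higher and 112 lower in c2.11, which is 1.29% of those tested (edgeR, adjusted p under the threshold of 0.05). Of these, 95 differed at least 2-fold and 44 at least 4-fold. By their calls against WT, 74 had changed the same way in both lines, 12 in opposite ways, 99 in c2.11 alone, 63 in c2.5 alone and 1 in neither. Of the 3124 genes called against WT in 1 line and not in the other, 2962 did not differ between the lines by this test. An unadjusted edgeR p below 0.05 was reached by 2789 of the 19358 tested genes, above the share of 0.05 that unchanged genes would give. The 249 calls may therefore miss differences between the lines. The 249 genes were spread over the chromosomes without a detectable difference (2000 permutations, p = 0.164). The number was 112, 87 and 123 without c2.11 replicates 1, 2 and 3, and 70, 92 and 80 without c2.5 replicates 1, 2 and 3. It was 442 with DESeq2 and 626 with only the 2 lines fitted.

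1 library of c2.5 differed from the rest of its line in a set of scarce genes. In c2.5 replicate 2, 53 genes were at least 4-fold above both other c2.5 libraries, while the same comparison within its own genotype gave 14 genes or fewer for each other line library and 20 or fewer for each WT library. Their median was 3.97 normalized CPM in that library, 0.232 and 0.0461 in c2.5 replicates 1 and 3, and 0.140, 0.0458 and 0.0933 in the c2.11 libraries. In WT replicates 1, 2 and 3 it was 5.98, 1.36 and 2.15. Of these 53 genes, 12 were called lower in both lines together and 20 in c2.11. Only genes past the low-count filter over all 9 libraries were searched. Genes scarce in the other line libraries could pass it through their WT counts, so these lower calls are partly built in. Without c2.5 replicate 2, 10713 genes were changed in both lines together, 8780 in c2.5 and 92 between the lines.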

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

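The test of low counts was chosen after the result was seen. The test of neighbouring genes was fixed before its result.

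The change against WT differed between the lines in 249 genes by the test of c2.11 against c2.5, and 12 genes were called in opposite directions in the 2 lines, all 12 of them among the 249. By quartile of mean CPM, 31.7% of them lay in the lowest (79 of 249, Wilson 95% interval 26.3 to 37.7%), 17.3% and 16.5% in the middle ones and 34.5% in the highest. The lowest quartile thus held more of them than an even spread would give, so low counts may add to their number. It held under 50% of them, a limit set afterwards. An even spread would also stay under that limit, so it cannot decide whether low counts caused most of the calls. With a stricter filter of at least 1 CPM in 6 libraries 172 genes differed, among 17482 tested. The genes of the highest quartile, at 45.7 CPM and more, are not scarce. The 249 genes did lie beside each other more often than in shuffled gene orders. In 16 adjacent pairs both genes were called, against 3.22 on average and 10 at most in 10000 shuffles within chromosomes. In 10 of the 16 pairs both genes differed the same way, and in the rest opposite ways. The shuffles gave 1.66 same-way pairs on average and 8 at most. Small stretches that differ between the lines, through the plants' background or local effects on neighbouring genes, may account for the 16 pairs. How many of the 249 genes lie in such stretches was not tested. No window of 20 tested genes held more than 3 of them. The 10 splits of the 6 line libraries are too few for a share under 0.05, with 249 genes in the real split, which 1 split reached, and 4 at most in the others.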

How the results depend on the processing

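Total count scaling and the removal of the 100 most abundant genes were chosen after seeing the data. The counts for both lines together (11052), c2.5 (9667), c2.11 (10569) and the genes changed the same way in both (8544) stayed within 1.5 times under DESeq2, median-of-ratios factors, both low-count filters, fits on the compared genotypes where they apply, the replicate block and total count scaling. Without single libraries they ranged from 9834 to 10713, 8516 to 9617, 9590 to 10456 and 7653 to 8554. Requiring a 2-fold change left 2790 genes for both lines together and 2286 for the genes changed the same way. DESeq2 and edgeR shared 10123 calls for both lines together, all 10123 in the same direction. Total count scaling shared 8623 of these 11052 calls, 8463 of them in the same direction. The number of genes that differ between the lines was 249 in the main setting, 442 with DESeq2, 626 with only the 2 lines fitted, and 70 to 356 without single libraries: 112, 87 and 123 without c2.11 replicates 1, 2 and 3, and 70, 92 and 80 without c2.5 replicates 1, 2 and 3. The counts of 70 to 123 each came without 1 line library, which leaves fewer samples of the lines compared. With the filter of 1 CPM in 6 libraries the number was 172. Without WT replicates 1, 2 and 3 the number was 356, 318 and 285. These counts, and the 626, came without 1 or all of the WT libraries. The WT libraries differed more among themselves than the line libraries and enter the shared estimate of the spread. DESeq2 gave 442 with all 9 libraries, and the cause of the counts above 249 was not tested. The SlZFP2 call for both lines together (0.76 on the log2 scale) ended with DESeq2 (0.76, adjusted p = 0.0808), median-of-ratios factors (0.76, adjusted p = 0.0504) and the replicate block (0.78, adjusted p = 0.0602). Without single libraries its value ranged from 0.60 to 1.05, with an adjusted p of 0.0176 to 0.173, and the cause was not tested. In c2.11 the SlZFP2 value ranged from 0.82 to 1.33 and its call ended without c2.11 replicate 2, WT replicate 2 or WT replicate 3 (highest adjusted p = 0.0887). In c2.5 it ranged from 0.31 to 0.77 and never passed. The sources used here do not say whether same-numbered libraries share more than a number. Correlations of their deviations from the genotype means ran from -0.27 to 0.23, and from 0.11 to 0.23 among the replicate 3 libraries. Between differently numbered libraries of different genotypes they ran from -0.26 to 0.35, a range that holds the replicate 3 values. The replicate block gave 10888, 9513, 10390 and 217 genes for both lines together, c2.5, c2.11 and the difference between lines. It changed no call of a named gene except that of SlZFP2. Without the 100 most abundant genes 10979 genes were called. The gene list alternatives were not run, because no list could be matched to the identifiers, and the 2 named genes that fell did not pass the stricter filter of 1 CPM in 6 libraries. SlZFP2 had 11 to 49 counts per library, which limits its precision.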

Other observations

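The tests on the 53 genes of c2.5 replicate 2, the longest run, the correlation by gap in gene number, total count scaling, the removal of the 100 most abundant genes and the counts of genes outside those 100 were chosen after seeing the data.

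A stretch of chromosome 2 was lower over a run of genes in the test of both edited lines against WT. From gene number 070920 to 071050 of that chromosome, 12 tested genes in a row were lower in the lines than in WT, the longest run of calls in 1 direction among the tested genes. Their log2 changes ran from -5.32 to -0.25 with a median of -2.18, and 1 of 200 shuffles of the gene order gave a run as long. With total count scaling 10 of the 12 were still called lower, and the highest value was 0.03. Neighbouring genes of similar sequence can share reads, so the single values within the run are uncertain. More generally, 18.9% of adjacent tested pairs were changed in the same direction, against 16.3% on average in shuffled orders, and the 3650 pairs exceeded the highest of 1000 shuffles (3304). Between neighbours whose gene numbers differ by 10 or less, log2 changes correlated at 0.15, against 0.05 for wider gaps, across pairs that are not independent.

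The 20 tested genes nearest to SlZFP2, 10 on each side, had a median log2 change of 0.057 (bootstrap 95% interval -0.04 to 0.18), below the 0.76 of SlZFP2 itself, with 5 of them higher and 15 not called.

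The number of changed genes is large for 1 edited gene. The larger share of a few abundant transcripts in WT would raise all other genes of the lines by 1 common amount. The shares of the 100 most abundant genes give a rise of 0.12 on the log2 scale. That is below the median change of 0.29 with total count scaling. With total count scaling, which leaves that rise in, 2888 genes outside the 100 most abundant were called lower, and with TMM, which takes it out, 5505 were called higher, so both counts argue against it as the cause. Removing those 100 genes left 57.0% of tested genes called but decides nothing, since TMM already trims such genes. The lowest count without a single library was 9834, which argues against 1 deviating library. Of 100 splits of the 9 libraries into 3 groups of 3, the real one included, only the real one (1 split) gave 11052 genes. That argues against an accident of how these libraries were grouped. It cannot exclude chance differences between plants, since the sources do not say whether the pools came from separate ones. The highest other was 10469, in the 1 drawn split that kept all WT libraries as the WT group, so the count rests mainly on WT standing apart. Splits that placed any WT library outside that group gave at most 4997. The same holds for the genes changed in both lines the same way, with 8544 in the real split (1 of 100). The split that kept all WT libraries as the WT group gave 8365, and the others gave at most 2. For c2.5 and c2.11 against WT the 10 splits each are too few for a share under 0.05, with 9667 and 10569 genes in the real split (1 split each) and 0 at most in the others. What stays open includes a batch, since 0 libraries have a label for batch, date, run or lane. A difference between WT and line plants in background, handling, growth or exact fruit stage cannot be told apart from the effect of the edit. The same holds for anything else that both lines share and WT lacks. A different cell makeup of the tissue was not tested.

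The 53 genes raised in c2.5 replicate 2 behaved alike in the WT libraries, which the 4-fold rule did not use. WT counts did enter the low-count filter, which the genes of the matched lists below had also passed. In WT, 88.7% of them (47 of 53) had the order replicate 1 over 3 over 2. In 10000 lists of other genes matched on mean WT CPM, the most common of the 6 orders held 25.3% on average and 45.3% at most, which argues against unrelated noise of single genes. A candidate explanation is RNA from 1 source, such as another tissue left at dissection, in a share that varied between libraries. A single source would give 1 common ratio between libraries. For WT replicates 1 and 3, the pair named for the test, the variance of the log2 ratio was 1.61 times that of a common ratio with counting noise, within the limit of 2. For WT replicates 1 and 2, weighed after its value was seen, it was 3.44 times, so this stays open. No marker list could be applied to name a tissue. The genes took 0.0374% of the counts of c2.5 replicate 2 and 0.0539% of those of WT replicate 1. Of the 53, 12 were called lower in both lines together, a small part of the 11052. Over all tested genes, the deviations of c2.5 replicate 2 and WT replicate 1 from their genotype means correlated at 0.35, the highest of all pairs of libraries. Whether what they share reaches genes beyond the 53 was not tested.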
